A study of Mus musculus with 12 samples.

How the data were processed

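Poly-A RNA was sequenced from lung tumours, adjacent lung tissue and sorted AT2 cells of mice, in 12 libraries that form 4 groups of 3. Per the labels' protocols, mRNA was captured on poly-T beads and made into libraries with a NEBNext Ultra RNA kit, which does not mark the strand of a transcript. The 2 deposited tables hold whole-number counts per gene, not normalised, 1 table for the 6 lung libraries and 1 for the 6 AT2 libraries. Per the submitters' processing notes, the tools were FastQC, Trimmomatic 0.39, HISAT2, StringTie 1.3.3b and DESeq2 1.28.1, on the mouse genome build GRCm38 (mm10). The step that turned alignments into counts, its strand setting and the annotation release are not given in the sources used here. Count intervals and floors therefore assume that 1 count is 1 read or read pair.

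Gene names and GRCm38 coordinates came from GENCODE M21. The lung table lists 56262 gene identifiers, of which 1121 matched no name and carried 0.0921% of the counts. The AT2 table lists 54532, of which 123 matched no name and carried 0.0289%. The tables share 54186 identifiers, so they were made from lists of genes that differ, and each was normalised and tested on its own. A level set beside one from the other table is a description and was not tested. Where 1 name belonged to several identifiers, the identifier with the most counts kept the name. Without strand, reads of overlapping or antisense genes cannot be told apart, which bears on the Meg3, Rian and Mirg transcripts and the microRNAs inside them. Reads of near-identical copies can be split or shared between them, which bears on the Cyp2c, Gsta, haemoglobin, H2, Ear and Hspa1 genes.

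Total counts were 65163100 to 77951014 per lung library and 15943084 to 18913242 per AT2 library. No pair of libraries within a group was near-identical: chi-square per degree of freedom, over genes with at least 20 counts, was 376 to 1164 for lung pairs, 45.9 to 94.0 for wild-type pairs and 7.23 to 10.8 for knockout AT2 pairs. The mice were separate animals by their numbers, and tumour and adjacent tissue with the same number came from the same animal. Deviations from the group means went together within each such pair (Pearson r across genes of 0.273 for mouse 102, 0.459 for mouse 217 and 0.366 for mouse 224), so the mouse numbers pair the lung samples.

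Genes were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood fit and test), after its filter on low counts and TMM normalisation, with Benjamini-Hochberg adjustment and a threshold of 0.05. Tumour was compared with adjacent tissue, and knockout AT2 cells with wild-type AT2 cells, each in the 6 libraries of its own table, with group as the only term. The labels state no paired fit, so the main fit was fixed without the mouse. It leaves out the pairing of the lung samples, and the fit with the mouse as a block is given as an alternative. Levels are CPM (counts scaled to a common library total) after TMM normalisation, given as mean ± SD over 3 libraries unless stated otherwise. A log2 fold change is given ± its standard error, with tumour or knockout as the numerator. Where a group had 0 counts in all of its libraries, the fold is a lower bound against a floor of 3 counts over that group. Such floors cover counting error only.

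For groups of genes, 44 lists of cell-type markers and processes were fixed before the data were examined, as were the tests, the named-gene rule and most of the alternative settings. All 765 members outside the sex list are in both tables. The cell-type lists cover AT2, AT1, club, ciliated, basal (squamous), neuroendocrine, T, resident T, cytotoxic, regulatory T and checkpoint, B and plasma, dendritic, endothelial, fibroblast, smooth muscle, heart muscle, mesothelial, fat and erythroid cells, alveolar macrophages, monocytes with other macrophages, and neutrophils. The process lists cover proliferation, tumour plasticity, the alveolar transitional state, RAS-MAPK output, NRF2 targets, antioxidant enzymes, oxidant-producing enzymes, p53 targets, DNA repair, respiration, glycolysis and hypoxia, lipid synthesis, cholesterol, unfolded protein response, early stress genes, MHC class I and II, interferon, NF-kB inflammation, matrix and mesenchymal transition, and Mediator subunits. Some genes stand in more than 1 list. A list of sex-linked genes served only to describe the animals. Lists with at least 5 tested members were tested two-sided against the other genes with camera (limma 3.58.1, preset correlation between genes 0.01) on log2 CPM with a prior count of 2, adjusted over the lists. Every list test was repeated with an estimated correlation and with fry, a rotation test of whether the members of a list move one way.

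The genes named were chosen by rule. Med23 came first. Then came the 8 genes higher and the 8 lower of largest fold among those that passed, had a mean of at least 5 CPM and did not overlap between groups, leaving out predicted genes and antigen receptor segments. Where none passed in a direction, the 4 of smallest p with a mean of at least 5 CPM were taken and described as not passing. Up to 4 members of smallest p were taken from each list, and some genes were named whatever their values: Med23, Itgae, Cd8a, Cd4, Sftpc, Scgb1a1, Nkx2-1, Trp63, Krt5, Mki67, Cdkn1a, Hmox1, Nqo1, Gpx3 and Sod2. Some genes that the rule names are not reported here. A gene outside the rule is said to have been chosen after its values were seen.

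Alternative settings were DESeq2 1.42.0, limma-voom with sample weights, DESeq2 size factors or library totals in place of TMM, no filter on low counts, a filter of at least 5 CPM in 3 libraries, a fold of at least 2, each library left out in turn, and the mouse as a block. The tests were tried on simulated counts made from the real means and library sizes with 200 changed genes. In the lung design (19275 genes) edgeR recovered 52% of genes changed 8-fold, 2% of those changed 4-fold and 0% of those changed 2-fold, with 1 false call among 28. In the AT2 design (13750 genes) it recovered 100% of 8-fold, 96% of 4-fold, 56% of 2-fold and 14% of 1.5-fold changes, with 5 false calls among 138. With 5 of 40 lists shifted 1.5-fold, camera with the preset correlation called 4 of them in the lung design and 5 in the AT2 design, and no other list. With an estimated correlation it called 0 in the lung design and 4 in the AT2 design, and fry called 0 and 5, with the 200 genes changed. The simulated shift was larger than the mean change of any list that passed in AT2 cells. The simulated genes were independent of each other, so these list calls do not show how often lists of correlated genes pass by error. Among the real lists the estimated correlation reached 0.970 (erythroid list, lung) and 0.559 (antioxidant enzymes, AT2 cells).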

Results

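The study dealt with C57BL/6 mice in which Med23, a subunit of the Mediator complex that links transcription factors to RNA polymerase II, was deleted in T cells. Lung tumours and adjacent normal lung tissue came from the same 3 knockout mice, numbered 102, 217 and 224, at 18 months of age. Alveolar type 2 (AT2) cells, the surfactant-producing cells of the alveolus, were sorted at 6 months from 3 wild-type mice (176, 177 and 190) and 3 knockout mice (175, 179 and 191). Each library is named by its group and mouse number. The tumour libraries held 73241534 counts (102), 77951014 (217) and 67632017 (224), and the adjacent libraries 73620767, 73749901 and 65163100 in the same order. The wild-type AT2 libraries held 16929255 (176), 18913242 (177) and 17253154 (190) counts, and the knockout AT2 libraries 16858412 (175), 18148829 (179) and 15943084 (191).

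Some libraries stood apart from others of their group. The surfactant gene Sftpc took 3.73%, 14.7% and 5.58% of the counts of tumours 102, 217 and 224, and 1.41%, 3.19% and 1.84% of those of the adjacent tissue of the same mice. Mitochondrial transcripts took 6.44% in tumour 217 and 2.05% to 3.89% in the other lung libraries. The first principal component of the lung libraries (52.9% of the variance) separated tumour from adjacent tissue, and the second (21.3%) separated both libraries of mouse 217 from the rest. In both of these libraries expression fell with gene length relative to the other lung libraries (Spearman rho across genes of -0.268 and -0.326, against 0.0489 to 0.219). Among AT2 libraries, the first component (45.6%) separated wild-type 177, at 64.6, from the other 5, at -14.6 to -11.3. The length trend was negative in wild-type 177 (-0.286) and wild-type 176 (-0.211) and 0.142 to 0.402 in the others.

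Med23 itself (ENSMUSG00000019984, chromosome 10, 24869986 to 24913681) was measured at 25.9, 18.3 and 36.8 CPM in tumours 102, 217 and 224 and at 29.8, 21.0 and 31.5 CPM in the adjacent tissue. The means were 27.0 ± 9.29 against 27.5 ± 5.65 CPM, with a log2 fold change of -0.02 ± 0.36 and an adjusted p of 0.982. In AT2 cells it was at 40.1, 34.4 and 46.4 CPM in wild-type 176, 177 and 190 and at 42.1, 45.7 and 46.5 CPM in knockout 175, 179 and 191 (log2 fold change 0.15 ± 0.15, adjusted p = 0.984). The deletion was in T cells, so Med23 in whole lung or in sorted AT2 cells checks none of the labels. Every animal was male by its transcripts: Xist, the RNA of the inactive X chromosome, stayed at or below 2.11 CPM in all 12 libraries. The Y-linked gene Ddx3y averaged 61.4 ± 6.34 against 50.2 ± 19.4 CPM in tumour and adjacent tissue, and the Y-linked Uty 30.4 against 33.5 CPM in knockout and wild-type AT2 cells.

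The first comparison asked what kind of tumours these were and how they differed from the lung around them. The tumours held more RNA of an imprinted non-coding region on chromosome 12, of AT2 cells, of RAS-MAPK output and of a tumour plasticity list, and less RNA of ciliated, club, AT1, endothelial, mesothelial, T and cytotoxic cells. The list results among these passed with camera's preset correlation, while with an estimated correlation none passed, at adjusted p = 0.228 to 0.432. With fry they passed (adjusted p = 0.00624 to 0.0161) except the T cell list (0.0926). Meg3, a maternally expressed long non-coding RNA, averaged 2527 ± 1141 CPM in tumours and 7.13 ± 3.13 CPM in adjacent tissue (n = 3 each), a log2 fold change of 8.47 ± 0.72. Sox9, a transcription factor of the embryonic distal lung, rose from 0.866 ± 0.356 to 79.4 ± 41.2 CPM (6.52 ± 0.58). Scgb1a1, the secretoglobin of club cells, fell 19.8-fold, from 25994 ± 10288 to 1309.9 ± 554 CPM (-4.31 ± 0.63). Foxj1, the transcription factor of multiciliated cells, fell from 166 ± 16.0 to 1.92 ± 1.33 CPM (-6.44 ± 0.66). In each of these 4 genes all 3 tumours lay on one side of all 3 adjacent libraries.

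Of 19995 genes tested with edgeR, 2007 passed, 571 of them higher (28.45%) and 1436 lower in tumours, and all 2007 differed by at least 2-fold. At an unadjusted p under 0.05 there were 4791 genes, and the smallest adjusted p was 0.00592. Scaling by library totals alone moved the median of all genes by -0.22 on the log2 scale and gave 2233 genes, of which 17.6% were higher. With the mouse as a block, 2980 genes passed, 1113 of them higher and 1867 lower, and 1719 passed in both fits. The median standard error of a log2 fold change was 0.52 without the block and 0.34 with it. In the simulated counts, the fit without the block recovered 2% of 4-fold and 0% of 2-fold changes. The number of genes that passed fell with each library left out, and least without tumour 217. Fewer libraries also mean less power, so a lost call need not come from the library left out. The number was 805 without tumour 102, 1854 without tumour 217 and 688 without tumour 224. It was 762 without adjacent 102, 879 without adjacent 217 and 598 without adjacent 224. Without both libraries of mouse 217 it was 847. Of 112 named genes that passed, 34 did so in all 6 of these smaller fits, and beside each of the others given as an example stand the libraries that ended its call when left out, 1 at a time.

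Among the genes of largest fold, 3 of the 8 higher in tumours belonged to the Dlk1-Meg3 region. Mirg, a microRNA host transcript, was at 96.7 ± 46.8 against 0.238 ± 0.0897 CPM in tumour and adjacent tissue (log2 fold change 8.66 ± 0.62, adjusted p = 0.00592) and Meg3 had the same adjusted p. Dlk1, which encodes a membrane protein of the Notch ligand family, was at 148 ± 143 against 0.634 ± 0.959 CPM (7.85 ± 1.54, adjusted p = 0.0229). Dlk1 was at 312 CPM in tumour 102 and at 71.1 and 59.5 CPM in tumours 217 and 224, and it did not pass without tumour 102, adjacent 217 and adjacent 224 (adjusted p up to 0.0700). Kng2, a kininogen gene, was at 406 ± 81.9 against 2.20 ± 1.18 CPM (chromosome 16, 22985854 to 23029482, log2 fold change 7.53 ± 0.60, adjusted p = 0.00592). Gja3, a gap junction gene known from the lens, was at 24.1 ± 12.1 against 0.0430 ± 0.0373 CPM (9.07 ± 1.0, adjusted p = 0.00627), and Tbx15, a T-box transcription factor, at 28.4 ± 8.77 against 0.0733 ± 0.0635 CPM (8.56 ± 0.98, adjusted p = 0.00664). Cyp2c40, a member of a cytochrome P450 family with near-identical copies, had 0 counts in adjacent tissue and 22.8 ± 26.5 CPM in tumours, at least 1748-fold higher (adjusted p = 0.0142). Cltrn, which encodes collectrin, had 0 counts in adjacent tissue and 2.02, 63.0 and 91.5 CPM in tumours 102, 217 and 224, at least 3998-fold higher by the means (adjusted p = 0.0205), and did not pass without adjacent 102 and adjacent 224 (adjusted p up to 0.0560). By the naming rule, all 3 tumours were above all 3 adjacent libraries for these 8 genes.

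The chromosome 12 region was looked at further after these values were seen. Of the genes within 1 Mb of Meg3 (chromosome 12, 109541001 to 109571726), those that rose lay between Dlk1 (chromosome 12, 109452823 to 109463336) and Dio3os (110275385 to 110278172). Rian, a non-coding RNA between Meg3 and Mirg, was at 854 CPM in tumours and 5.36 CPM in adjacent tissue (log2 fold change 7.31 ± 0.67, adjusted p = 0.00592), and Dio3os was at 4.57 and 0.545 CPM (3.06 ± 0.74, adjusted p = 0.0409). Dio3os did not pass without tumour 102, tumour 217, adjacent 102, adjacent 217 and adjacent 224 (adjusted p up to 0.139), nor with limma-voom (0.0835), without the filter on low counts (0.0618) or without both libraries of mouse 217 (0.169). Rtl1, transcribed from the opposite strand inside the region, did not pass (3.78 ± 1.58, adjusted p = 0.196), nor did Dio3 at its far end (0.33 ± 0.93, adjusted p = 0.884). The flanking genes Begain (-3.58 ± 1.43, adjusted p = 0.175), Yy1 (0.49 ± 0.29, adjusted p = 0.378), Wars (-0.18 ± 0.48, adjusted p = 0.879) and Ppp2r5c (0.32 ± 0.34, adjusted p = 0.666) did not pass either. The libraries carry no strand, so reads of transcripts that overlap here cannot be told apart.

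**Figure D1:**
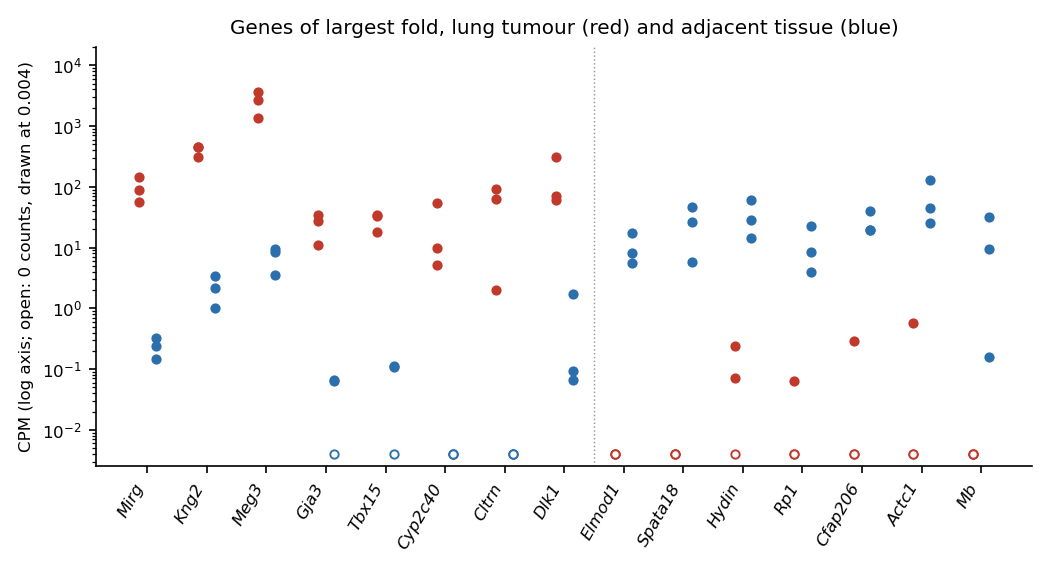
Expression of 8 genes higher and 7 lower in tumours among those of largest fold, in the 3 tumours (red) and the 3 adjacent lung samples (blue), in CPM on a log axis, 1 point per library, with open points at the lower edge for 0 counts. For each of these genes the 3 tumours lie on one side of the 3 adjacent samples, with Dlk1, Cltrn and Cyp2c40 spread widely among tumours.

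**Figure D2:**
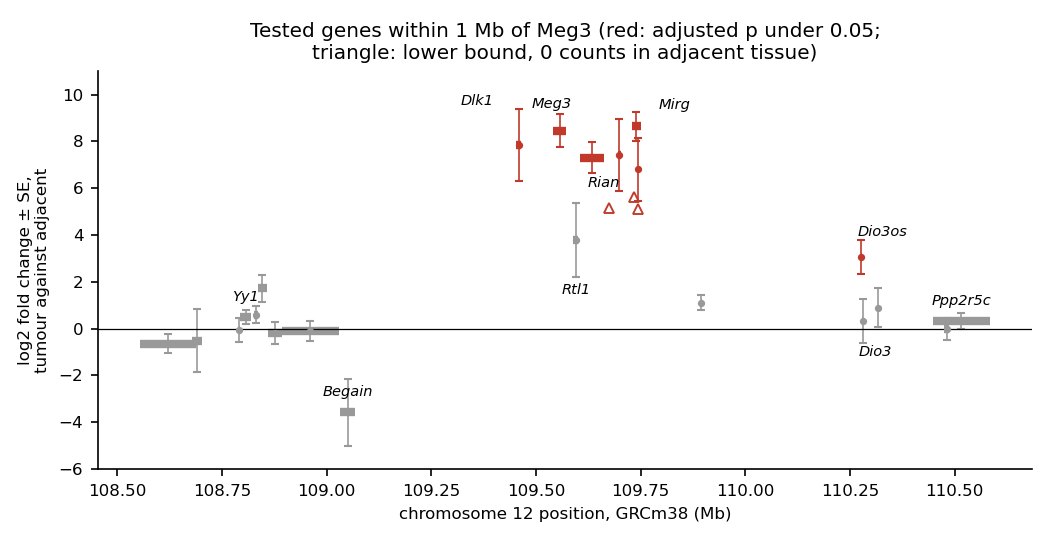
Log2 fold change of tumour against adjacent tissue (± SE) for each tested gene within 1 Mb of Meg3, by position on chromosome 12 (GRCm38, Mb), with genes of adjusted p under 0.05 in red. Open triangles are lower bounds for 3 genes with 0 counts in adjacent tissue, and the genes in red lie between Dlk1 and Dio3os.

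Of the genes of largest fold that were lower in tumours, 7 are described, all with the 3 tumours below the 3 adjacent libraries and several of them genes of airway cilia or muscle. Spata18 had 0 counts in tumours and 26.2 ± 20.3 CPM in adjacent tissue, at least 1764-fold lower (adjusted p = 0.00998), and Elmod1 0 counts and 10.3 ± 6.14 CPM, at least 694-fold lower (adjusted p = 0.00763). Hydin, a protein of the ciliary axoneme, was at 0.103 ± 0.123 against 34.3 ± 23.2 CPM (log2 fold change -8.38 ± 1.20, adjusted p = 0.0101) and Rp1, a microtubule-associated protein, at 0.0212 ± 0.0368 against 11.8 ± 9.86 CPM (-9.06 ± 1.37, adjusted p = 0.0113). Cfap206, a ciliary protein, was at 0.0955 ± 0.165 against 26.0 ± 11.7 CPM (-8.10 ± 1.45, adjusted p = 0.0172) and did not pass without adjacent 102 and adjacent 224 (adjusted p up to 0.0580). Actc1, cardiac actin, was at 0.191 ± 0.331 against 66.6 ± 54.7 CPM (-8.46 ± 1.69, adjusted p = 0.0239) and did not pass without tumour 102, tumour 224, adjacent 102 and adjacent 224 (adjusted p up to 0.0713). Mb, myoglobin, had 0 counts in tumours and 13.7 ± 16.0 CPM in adjacent tissue, at least 919-fold lower (adjusted p = 0.0420), and did not pass without tumour 102, tumour 217, tumour 224, adjacent 102 and adjacent 224 (adjusted p up to 0.103).

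Of the 41 lists tested in the lung libraries, 25 differed between tumour and adjacent tissue, 7 of them up and 18 down, with camera and its preset correlation. The mean log2 CPM of the list separated all 3 tumours from all 3 adjacent libraries in 20 of the 25, the exceptions being the B and plasma cell, neutrophil, DNA repair, respiration and MHC class II lists. Within each mouse the means of these 5 also moved one way, lower in the tumour for the first 2 lists named and higher for the other 3. With an estimated correlation no list passed (0 lists, 8 at an unadjusted p under 0.05, smallest adjusted p = 0.228), and with fry 15 did. These were 14 of the 25 and the Mediator subunits; the T cell, B and plasma cell, neutrophil, dendritic, fibroblast, smooth muscle, erythroid, DNA repair, respiration, glycolysis and MHC class II lists did not pass with fry (adjusted p = 0.0612 to 0.447). Of the 25, 18 passed in every fit with 1 library left out. Counts of single members moved more: over all lists, 41 members rose and 99 fell with all libraries, 17 and 36 without tumour 102, 38 and 114 without tumour 217, 14 and 34 without tumour 224, 13 and 51 without adjacent 102, 9 and 48 without adjacent 217, and 5 and 41 without adjacent 224. Unless said otherwise, a gene said to have risen or fallen had all 3 tumours on one side of all 3 adjacent libraries, which chance alone gives in 10% of genes.

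RAS-MAPK output had the smallest adjusted p among the process lists with camera's preset correlation. With fry the plasticity list had a smaller adjusted p (0.00624 against 0.00671). Of the 18 tested RAS-MAPK members, 10 rose, none fell and 8 did not pass, and 15 rose adjusted over the list alone (median log2 fold change 1.58, adjusted p = 4.99e-08, and adjusted p = 0.228 with an estimated correlation). With 1 library left out, 1 to 7 of these members rose. Etv4, an ETS factor induced by MAPK signalling, rose (65.9 ± 28.8 against 0.963 ± 0.396 CPM, log2 fold change 6.10 ± 0.59, adjusted p = 0.00592). Spred1 and Spry2, feedback inhibitors of the pathway, rose too. Spred1 was at 318 against 79.8 CPM and did not pass without tumour 102, tumour 224, adjacent 217 and adjacent 224 (adjusted p up to 0.0836). Spry2 was at 99.2 against 26.3 CPM and did not pass without tumour 224, adjacent 217 and adjacent 224 (adjusted p up to 0.0854). Ereg, a ligand of the EGF receptor, was at 21.9 against 0.539 CPM and did not pass without adjacent 102, adjacent 217 and adjacent 224 (adjusted p up to 0.0820).

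The tumour plasticity list rose with 7 of 20 members up, 1 down and 12 not passing, and 11 up and 2 down adjusted over the list alone (median 1.65, adjusted p = 8.01e-05, and adjusted p = 0.228 with an estimated correlation). Besides Sox9, the members that rose included Cldn2, a claudin that forms cation pores (161 ± 86.7 against 3.02 ± 0.792 CPM, log2 fold change 5.74 ± 0.60, adjusted p = 0.00592), and Hnf4a, a gut and liver transcription factor (8.25 ± 1.0 against 0.497 ± 0.254 CPM, log2 fold change 4.05 ± 0.58, adjusted p = 0.010). Krt18, a keratin of simple epithelium, rose (633 ± 161 against 115 ± 27.1 CPM, log2 fold change 2.45 ± 0.37, adjusted p = 0.0111) and did not pass without adjacent 224 (adjusted p up to 0.0529). The member that fell, named after its values were seen, was Plaur, the urokinase receptor (33.3 against 88.1 CPM, log2 fold change -1.40 ± 0.36, adjusted p = 0.04996). Plaur did not pass without tumour 102, tumour 217, tumour 224, adjacent 217 and adjacent 224 (adjusted p up to 0.167), nor with DESeq2 size factors (0.0587) or without the filter on low counts (0.0669). With the block 8 members rose and 2 fell.

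The AT2 list also rose, with 4 of 20 members up, 1 down and 15 not passing, 11 up and 1 down adjusted over the list alone and 11 up with the mouse as a block (median 1.45, adjusted p = 2.35e-05, and adjusted p = 0.245 with an estimated correlation). Sftpb, surfactant protein B, was at 19565 ± 3634 against 3374 ± 679 CPM (2.54 ± 0.46, adjusted p = 0.0177) and did not pass without tumour 224, adjacent 102, adjacent 217 and adjacent 224 (adjusted p up to 0.0780). Lamp3 and Ctsh, proteins of lamellar bodies and lysosomes, rose with all libraries. Lamp3 did not pass without tumour 102, tumour 224, adjacent 102, adjacent 217 and adjacent 224 (adjusted p up to 0.116). Nor did Ctsh pass without tumour 102, tumour 224, adjacent 102, adjacent 217 and adjacent 224 (adjusted p up to 0.110). The member that fell, also named after its values were seen, was Lyz1, a lysozyme gene (10.1 against 99.7 CPM, log2 fold change -3.30 ± 0.75, adjusted p = 0.0340). Lyz1 did not pass without tumour 217, tumour 224, adjacent 102, adjacent 217 and adjacent 224 (adjusted p up to 0.102). Sftpc, surfactant protein C, was at 92251 ± 78993 against 20156 ± 9929.8 CPM (2.19 ± 0.78, adjusted p = 0.131, 0.0462 with the mouse as a block). Nkx2-1, the transcription factor of lung epithelium and a marker of adenocarcinoma, was at 661 ± 326 against 246 ± 78.2 CPM (1.43 ± 0.45, adjusted p = 0.0928, 0.0265 with the block). Neither passed without the block. The basal and squamous marker Krt5 had 0 counts in tumours and 38 in adjacent tissue and was not tested, and Trp63 was at 0.287 against 0.469 CPM (adjusted p = 0.736). The squamous list had 3 tested members and was not tested.

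Glycolysis and hypoxia genes rose as a list, with 4 of 22 members up, none down and 18 not passing, 8 up adjusted over the list alone and 8 up with the mouse as a block (median 1.0, adjusted p = 0.000455, and adjusted p = 0.432 with an estimated correlation). Pfkl, a phosphofructokinase, was at 310.2 against 88.5 CPM and did not pass without tumour 102, adjacent 102, adjacent 217 and adjacent 224 (adjusted p up to 0.0649). Respiration, DNA repair and MHC class II rose as lists with few or no members passing. Of 43 respiration genes 0 passed, and 2 rose with the block (median 0.40, adjusted p = 0.00580, and adjusted p = 0.546 with an estimated correlation). This list did not pass without tumour 217 (adjusted p = 0.260), adjacent 102 (0.0783) or adjacent 224 (0.0597). Of 30 DNA repair genes 0 passed, and 1 rose with the block (median 0.36, adjusted p = 0.0283, and adjusted p = 0.394 with an estimated correlation). This list did not pass without tumour 217 (0.0683), tumour 224 (0.0520) or adjacent 102 (0.0763). Of 10 MHC class II genes 1 rose, 1 fell and 8 did not pass, and 4 rose with the block (median 0.94, adjusted p = 0.0202, and adjusted p = 0.485 with an estimated correlation). The list did not pass without tumour 217 (0.0651) or adjacent 102 (0.0981). H2-DMb2, which helps load peptides on class II molecules, rose (125 against 28.9 CPM, log2 fold change 2.11 ± 0.44) but did not pass without tumour 102, tumour 224, adjacent 217 and adjacent 224 (adjusted p up to 0.0828). H2-Ob, which inhibits that loading in B cells, fell (2.71 against 21.8 CPM, log2 fold change -3.01 ± 0.58) but did not pass without tumour 102, tumour 224, adjacent 217 and adjacent 224 (adjusted p up to 0.0800).

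The ciliated, club, AT1 and neuroendocrine lists fell. Of 15 tested ciliated cell genes 12 fell and 3 did not pass, and all 15 fell adjusted over the list alone (median -5.50, adjusted p = 6.06e-12, and adjusted p = 0.289 with an estimated correlation). Their summed level was 12.3, 44.7 and 13.7 CPM in tumours 102, 217 and 224 and 1056, 910 and 565 CPM in the adjacent tissue. Besides Foxj1, Tmem212 (0.485 ± 0.243 against 33.4 ± 10 CPM, log2 fold change -6.11 ± 0.55, adjusted p = 0.00592) and Dnah9, an axonemal dynein (0.849 ± 0.175 against 39.3 ± 22.5 CPM, log2 fold change -5.53 ± 0.54, adjusted p = 0.00592), fell. Of 13 club cell genes 7 fell, 6 did not pass and 7 fell adjusted over the list alone (median -3.47, adjusted p = 0.000317, and adjusted p = 0.228 with an estimated correlation). Aldh1a1, a retinaldehyde dehydrogenase, fell (39.7 ± 15.1 against 701 ± 414 CPM, log2 fold change -4.14 ± 0.56, adjusted p = 0.00898). Scgb3a2, another secretoglobin, fell (4.80 against 495 CPM, log2 fold change -6.69 ± 1.16) but did not pass without tumour 102 (adjusted p up to 0.0621). Of 15 AT1 genes 7 fell, 8 did not pass and 10 fell adjusted over the list alone (median -1.57, adjusted p = 2.35e-05, and adjusted p = 0.314 with an estimated correlation). Examples were Rtkn2 (9.33 ± 5.01 against 107 ± 31.0 CPM, log2 fold change -3.51 ± 0.47, adjusted p = 0.00898) and Clic5 (65.5 ± 29.1 against 649 ± 332 CPM, log2 fold change -3.31 ± 0.54, adjusted p = 0.0137). Of 10 neuroendocrine genes 5 fell, 5 did not pass and 5 fell adjusted over the list alone, while 2 fell with the block (median -2.37, adjusted p = 2.35e-05, and adjusted p = 0.228 with an estimated correlation). Pcsk1, a prohormone convertase, had 0 counts in tumours and a mean of 0.959 CPM in adjacent tissue, at least 64.5-fold lower (adjusted p = 0.0152, 0.0536 with the block), and did not pass without adjacent 102, adjacent 217 and adjacent 224 (adjusted p up to 0.0598).

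Vessel and mesothelial genes fell as well. Of 20 endothelial genes 14 fell, 6 did not pass and 17 fell adjusted over the list alone (median -2.11, adjusted p = 7.56e-11, and adjusted p = 0.228 with an estimated correlation). Their summed level was 1347, 1476 and 1209 CPM in tumours and 8829, 6016 and 5032 CPM in adjacent tissue. Sox17, an endothelial transcription factor (7.21 ± 1.79 against 90.1 ± 23.8 CPM, log2 fold change -3.64 ± 0.37, adjusted p = 0.00592), Cldn5, an endothelial tight junction protein (38.1 ± 16.1 against 540 ± 99.6 CPM, log2 fold change -3.83 ± 0.44, adjusted p = 0.00664), and Calcrl, the receptor of adrenomedullin (45.1 ± 16.0 against 715 ± 393 CPM, log2 fold change -3.99 ± 0.54, adjusted p = 0.00920), were among those that fell. Of 8 mesothelial genes 5 fell, 3 did not pass and all 8 fell adjusted over the list alone (median -4.05, adjusted p = 2.62e-06, and adjusted p = 0.270 with an estimated correlation). Muc16, a mucin of the mesothelium, had 0 counts in tumours and 3.97 ± 1.67 CPM in adjacent tissue, at least 267-fold lower (adjusted p = 0.00871). Of 16 fibroblast genes 1 rose, 2 fell and 13 did not pass, with 1 up and 7 down adjusted over the list alone and 6 down with the block (median -1.26, adjusted p = 0.00371, and adjusted p = 0.432 with an estimated correlation). The member that rose was Cthrc1, a collagen triple helix protein of fibroblasts in injured tissue (23.6 ± 8.02 against 2.73 ± 0.960 CPM, log2 fold change 3.11 ± 0.47, adjusted p = 0.0113). Of 8 smooth muscle genes 3 fell and 5 did not pass (3 adjusted over the list alone, median -1.59, adjusted p = 0.0125, and adjusted p = 0.485 with an estimated correlation). This list did not pass without tumour 224 (0.0577) or adjacent 102 (0.0921). Of 7 heart muscle genes, which the lung expresses around pulmonary veins, 3 fell, 4 did not pass and 6 fell adjusted over the list alone (median -4.39, adjusted p = 0.000933, and adjusted p = 0.394 with an estimated correlation). Of 19 matrix and mesenchymal transition genes 2 fell, 17 did not pass, 1 rose and 6 fell adjusted over the list alone, and 5 fell with the block (median -1.14, adjusted p = 0.0293, and adjusted p = 0.270 with an estimated correlation). Mmp2, a gelatinase, fell (24.3 against 123 CPM, log2 fold change -2.33 ± 0.35). That list did not pass without tumour 217 (0.0995), tumour 224 (0.0956), adjacent 217 (0.0812) or adjacent 224 (0.0558). Of 7 red blood cell genes 0 passed, 3 fell adjusted over the list alone and 6 fell with the block (median -3.44, adjusted p = 0.00230, and adjusted p = 0.432 with an estimated correlation).

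Among immune lists, those of cytotoxic lymphocytes, T cells, B and plasma cells, dendritic cells and neutrophils fell. Of 14 cytotoxic lymphocyte genes 5 fell, 9 did not pass and 10 fell adjusted over the list alone (median -2.63, adjusted p = 2.46e-06, and adjusted p = 0.228 with an estimated correlation). Prf1, perforin, fell (0.235 against 3.97 CPM, log2 fold change -4.07 ± 0.78) but did not pass without adjacent 102, adjacent 217 and adjacent 224 (adjusted p up to 0.0700). Of 20 general T cell genes 2 fell, 18 did not pass, 9 fell adjusted over the list alone and 8 fell with the block (median -1.62, adjusted p = 2.76e-05, and adjusted p = 0.432 with an estimated correlation). Their summed level was 66.2, 126 and 53.8 CPM in tumours and 114, 329 and 173 CPM in adjacent tissue. Cd8a, the co-receptor of cytotoxic T cells, was at 1.33 ± 0.967 against 7.89 ± 3.95 CPM (-2.57 ± 0.72, adjusted p = 0.0646, 0.0204 with the block, 0.0357 without tumour 217 and 0.0341 with library totals alone). Cd4 was at 2.44 ± 1.62 against 6.79 ± 4.88 CPM (-1.47 ± 0.83, adjusted p = 0.346). Itgae, the CD103 integrin of tissue-resident T cells, was at 6.67 ± 3.44 against 9.89 ± 2.26 CPM (-0.57 ± 0.48, adjusted p = 0.557), a difference within the spread of the libraries. The resident T cell list did not pass (0 of 12 members, 1 up and 1 down with the block, median -1.07, adjusted p = 0.0836), but did without tumour 102 (0.0394). With an estimated correlation its adjusted p was 0.432. Of 17 B and plasma cell genes 4 fell, 13 did not pass and 8 fell adjusted over the list alone (median -2.62, adjusted p = 0.000332, and adjusted p = 0.432 with an estimated correlation). Their summed level was 1241, 3092 and 162 CPM in tumours and 607, 7924 and 2484 CPM in adjacent tissue (mice 102, 217 and 224), higher in the tumour of mouse 102 only, while their mean log2 CPM was lower in the tumour of every mouse (1.81, 3.47 and 0.85 against 3.27, 5.55 and 4.97). Ighd, the IgD heavy chain, fell (1.31 against 19.1 CPM, log2 fold change -3.86 ± 0.63) but did not pass without tumour 102 and tumour 224 (adjusted p up to 0.0513). Of 11 dendritic cell genes 2 fell, 9 did not pass and 3 fell adjusted over the list alone (median -1.55, adjusted p = 0.00881, and adjusted p = 0.420 with an estimated correlation). This list did not pass without adjacent 217 (0.0567). Of 14 neutrophil genes 1 fell, 13 did not pass and 1 fell adjusted over the list alone, while 1 rose and 4 fell with the block (median -2.19, adjusted p = 0.0283, and adjusted p = 0.485 with an estimated correlation). The list did not pass without tumour 224 (0.148), adjacent 102 (0.0576), adjacent 217 (0.229) or both libraries of mouse 217 (0.0964).

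Interferon-stimulated genes fell, 7 of 25, with 18 not passing and 9 down adjusted over the list alone (median -1.14, adjusted p = 0.000332, and adjusted p = 0.432 with an estimated correlation). Usp18, a protease that limits interferon signalling (3.44 ± 0.611 against 24.9 ± 2.97 CPM, log2 fold change -2.85 ± 0.34, adjusted p = 0.00738), and Gbp2, a guanylate-binding protein (12.1 ± 2.11 against 70.5 ± 23.0 CPM, log2 fold change -2.54 ± 0.35, adjusted p = 0.00981), were among them. Cholesterol synthesis and uptake genes fell too, 6 of 20, with 14 not passing, 8 down adjusted over the list alone and 11 down with the block (median -0.89, adjusted p = 6.31e-05, and adjusted p = 0.228 with an estimated correlation). Sqle, squalene epoxidase, fell (20.4 ± 3.39 against 65.4 ± 11.1 CPM, log2 fold change -1.68 ± 0.30, adjusted p = 0.0172) but did not pass without tumour 102, tumour 224, adjacent 217 and adjacent 224 (adjusted p up to 0.0732). Idi1, isopentenyl diphosphate isomerase, fell (13.9 against 54.7 CPM, log2 fold change -1.98 ± 0.34) but did not pass without tumour 224, adjacent 102 and adjacent 224 (adjusted p up to 0.0618).

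The antioxidant lists did not pass as groups. With fry the adjusted p was 0.0720 for NRF2 targets and 0.759 for enzymes that remove superoxide and peroxides. Of 24 NRF2 targets 3 rose and 21 did not pass, with 4 up and 3 down adjusted over the list alone and 4 up and 2 down with the block (median 0.20, adjusted p = 0.214). Me1, malic enzyme, rose (645 against 105 CPM, log2 fold change 2.62 ± 0.45) but did not pass without adjacent 102, adjacent 217 and adjacent 224 (adjusted p up to 0.0660). Gsta4, a glutathione transferase, rose (241 against 56.3 CPM, log2 fold change 2.10 ± 0.36) but did not pass without adjacent 102 and adjacent 224 (adjusted p up to 0.0685). Nqo1, a quinone reductase, was at 1.26 against 4.78 CPM (-1.92 ± 0.52, adjusted p = 0.0595, 0.0420 with the block, 0.0411 without tumour 217 and 0.0296 with library totals alone). Hmox1, haem oxygenase, was at 163 against 72.6 CPM (1.16 ± 0.40, adjusted p = 0.117). Of 22 enzymes that remove superoxide and peroxides 2 rose, 1 fell and 19 did not pass, with 2 up and 1 down adjusted over the list alone and 3 up and 4 down with the block. The median was 0.04, the mean -0.10 and the test pointed up (adjusted p = 0.416). Gpx3, a secreted glutathione peroxidase, was at 385 against 1472 CPM (-1.94 ± 0.76, adjusted p = 0.168, 0.0257 with the block and 0.0352 without tumour 217). Sod2, mitochondrial superoxide dismutase, was at 95.4 against 109.6 CPM (adjusted p = 0.737). Of 13 oxidant-producing enzymes 2 rose and 11 did not pass, with 2 up and 4 down adjusted over the list alone and 2 up and 1 down with the block. As a list they leaned down, with 10 members lower, a median of -1.37 and the test pointing down. Adjusted p was 0.185, 0.0312 without adjacent 102 and 0.485 with an estimated correlation.

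The other lists did not pass either. Proliferation had 0 of 28 members passing, and 1 up with the block (median 0.32, adjusted p = 0.0616), with Mki67 at 33.1 against 26.6 CPM (adjusted p = 0.802). The list passed with the block (0.0273), without tumour 102 (0.00872), without adjacent 217 (0.0118) and without adjacent 224 (0.0228), but not with an estimated correlation (0.630, and 0.679 with the block). MHC class I (1 of 13 members down, 1 up and 3 down with the block, adjusted p = 0.0668) passed with the block (0.0238), without adjacent 102 (0.00649) and with a filter of 5 CPM (0.0250), but not with an estimated correlation (0.485, and 0.679 with the block). Alveolar macrophage genes (2 of 15 down, adjusted p = 0.0639) passed without tumour 102 (0.0196), without adjacent 102 (0.00285), with that filter (0.0250) and with the length trend removed (0.0422). Monocyte and macrophage genes (0 of 17, 1 down with the block, adjusted p = 0.336) passed without adjacent 102 (0.00329), as did NF-kB inflammation genes (1 of 18 down, 3 with the block, adjusted p = 0.315, 0.0267). The transitional alveolar list (2 of 18 up, 4 with the block, adjusted p = 0.124) passed without both libraries of mouse 217 (0.0268). With an estimated correlation the adjusted p was 0.485 for alveolar macrophage, 0.743 for monocyte and macrophage, 0.7145 for NF-kB and 0.432 for transitional genes. Regulatory T cell and checkpoint genes (1 of 12 up, 0.238), p53 targets (3 of 25 up and 2 down, 0.315), unfolded protein response (2 of 20 up, 0 with the block, 0.214), early stress genes (1 of 20 down, 1 up and 3 down with the block, 0.185) and lipid synthesis (2 of 20 up, 4 up and 2 down with the block, median -0.10, mean 0.16, test up, 0.359) passed in no setting run, the last values in brackets being adjusted p. Of 30 Mediator subunits 0 passed and 1 rose with the block, and the list did not pass with camera (adjusted p = 0.0901). It passed upward with fry (adjusted p = 0.0458, and adjusted p = 0.331 with an estimated correlation), and its mean was higher in all 3 tumours than in all 3 adjacent libraries. Cdkn1a, a p53 target that stops the cell cycle, was at 232 against 169 CPM (adjusted p = 0.770). The fat list had 3 tested members, of which 1 fell, and was not tested.

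**Figure D3:**
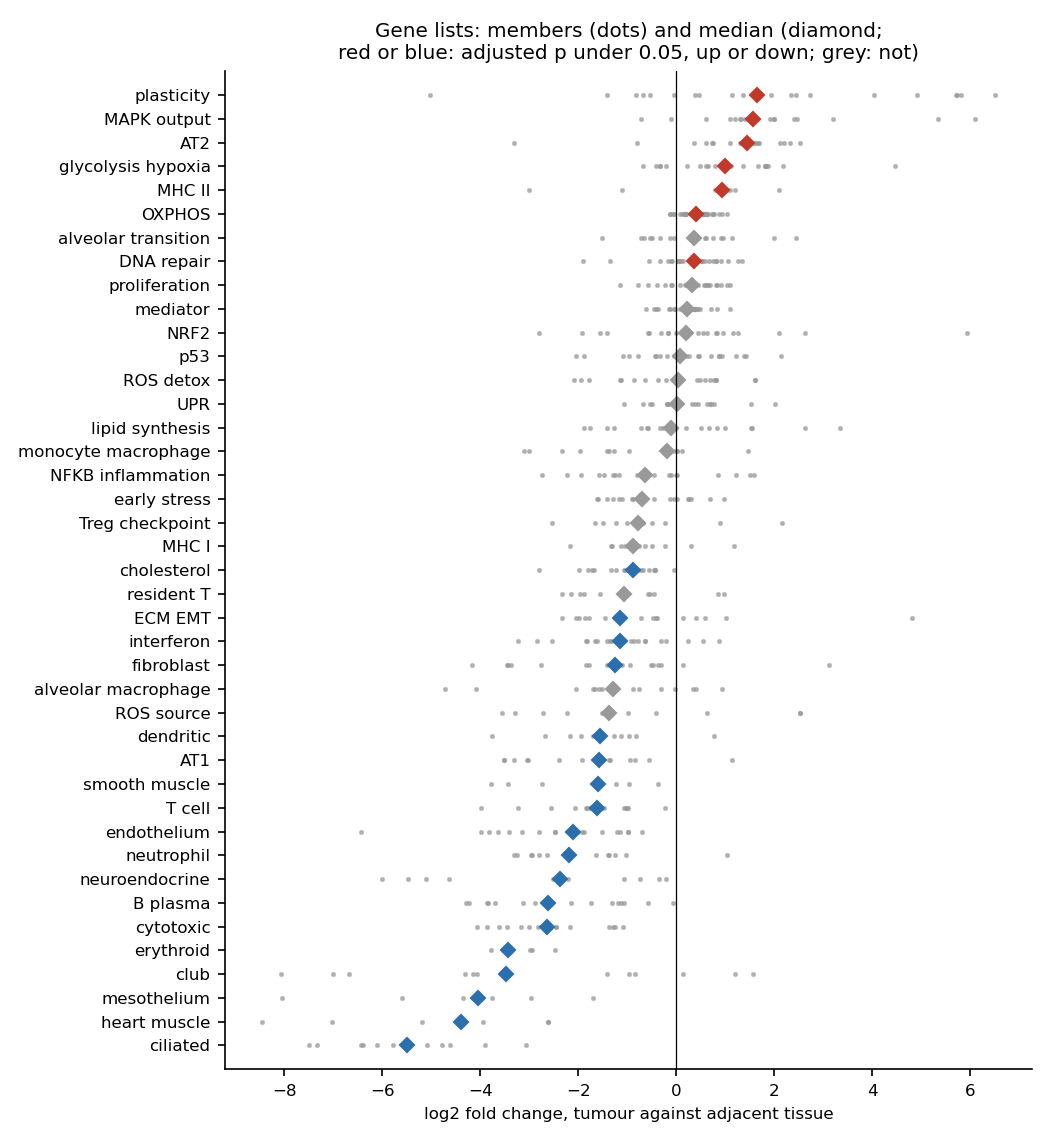
Log2 fold change of tumour against adjacent tissue for each tested member of the gene lists (dots, members with 0 counts in a group at their bound), with the median of each list as a diamond, red for lists that passed upward, blue downward and grey for the rest, by camera with the preset correlation. The plasticity, RAS-MAPK output and AT2 lists have the highest medians, and the ciliated, heart muscle and mesothelial lists the lowest.

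The second comparison asked how AT2 cells of the knockout mice differed from wild-type ones at 6 months, an age the study design places before tumour formation. No single gene passed, and 4 lists were slightly lower in knockout cells with camera's preset correlation: enzymes that remove superoxide and peroxides, NRF2 targets, respiration and proliferation. With an estimated correlation none of the 4 passed (adjusted p = 0.724 for each), nor with fry (0.689 for each), and without wild-type 177 only proliferation did. Of 14053 genes tested with edgeR 0 passed, against 347 at an unadjusted p under 0.05 (185 higher and 162 lower in knockout cells), and the smallest adjusted p was 0.447. DESeq2 and limma-voom each called 1 gene, the predicted microRNA Gm23935, at 33.3 CPM in knockout and 64.7 CPM in wild-type cells (adjusted p = 0.000514 and 0.0326). Without the filter on low counts edgeR called 17 genes, 11 higher and 6 lower. Without wild-type 176 it called 1, Spink5 (adjusted p = 0.00420), which was at 45.6 CPM in wild-type 176 and 0 in wild-type 177 and 190. These single genes were looked up after their values were seen. The median standard error of a log2 fold change was 0.20. In the simulated counts edgeR recovered 96% of 4-fold and 56% of 2-fold changes. Those genes were independent of each other, 200 of them were changed, and each had the same dispersion in both groups. The real wild-type libraries differed more from each other than the knockout ones did. The simulated shares may therefore not hold for the real AT2 libraries.

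The genes of smallest p in each direction did not pass. On the higher side these were Mrc2, a collagen-binding receptor (68.0 ± 8.75 against 36.6 ± 9.46 CPM, log2 fold change 0.89 ± 0.20, adjusted p = 0.984), Pcdhgb6, a protocadherin (15.2 against 7.18 CPM, log2 fold change 1.08 ± 0.26), Hspa1a, an inducible heat shock protein with a near-identical copy (70.0 against 31.1 CPM, log2 fold change 1.17 ± 0.29), and Zc3h3 (15.6 against 9.61 CPM, log2 fold change 0.70 ± 0.18). Without the filter on low counts Mrc2 (log2 fold change 0.90, adjusted p = 0.000358), Pcdhgb6 (1.09, 0.00403) and Hspa1a (1.17, 6.11e-08) passed. On the lower side they were Atp6v0a4, a proton pump subunit (3.90 ± 0.667 against 8.66 ± 0.448 CPM, log2 fold change -1.15 ± 0.23, adjusted p = 0.984), Pgrmc1 (14.2 against 23.5 CPM, log2 fold change -0.73 ± 0.17), Hopx, a homeobox gene of AT1 cells (6.54 against 11.6 CPM, log2 fold change -0.82 ± 0.24), and Lars2, a mitochondrial leucyl-tRNA synthetase (21.6 against 33.1 CPM, log2 fold change -0.62 ± 0.19). Sftpc was at 72384 ± 1084 against 91182 ± 18663 CPM in knockout and wild-type cells (-0.33 ± 0.20), Nkx2-1 at 805 against 731 CPM (0.14 ± 0.15), Scgb1a1 at 457 against 417 CPM (0.13 ± 0.16) and Mki67 at 12.1 against 14.4 CPM (-0.24 ± 0.43). Among antioxidant genes, Hmox1 was at 84.5 against 85.7 CPM, Nqo1 at 1.23 against 0.808, Sod2 at 88.2 against 98.3 and Gpx3 at 1.26 against 1.87, and the p53 target Cdkn1a was at 40.6 against 40.2 CPM. Cd4, Cd8a, Itgae, Krt5 and Trp63 were too low to test.

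Of 32 lists tested in AT2 cells, 4 passed, all lower in knockout cells, with small mean changes and with no single member passing. For 21 enzymes that remove superoxide and peroxides, 20 were lower (mean log2 fold change -0.21, adjusted p = 0.00326, and adjusted p = 0.724 with an estimated correlation), such as the peroxiredoxin Prdx6 (336 against 406 CPM, log2 fold change -0.27 ± 0.14). For 43 respiration genes, 38 were lower (mean -0.14, adjusted p = 0.00475, and adjusted p = 0.724 with an estimated correlation). For 27 proliferation genes, 20 were lower (mean -0.23, adjusted p = 0.00909, and adjusted p = 0.724 with an estimated correlation). An example is the replication helicase subunit Mcm6 (26.2 against 34.0 CPM, log2 fold change -0.38 ± 0.14). For 21 NRF2 targets, 19 were lower (mean -0.16, adjusted p = 0.0325, and adjusted p = 0.724 with an estimated correlation), such as the glutathione transferase Gstm1 (67.5 against 90.8 CPM, log2 fold change -0.43 ± 0.14). In none of the 4 did the list mean separate all 3 knockout from all 3 wild-type libraries. With the length trend removed, NRF2 (0.0612) and respiration (0.0765) did not pass. The antioxidant list did not pass without wild-type 177 (0.677) or knockout 191 (0.0591). Respiration did not pass without wild-type 176 (0.0765), wild-type 177 (0.816) or knockout 191 (0.0867). Proliferation did not pass without wild-type 176 (0.0765), wild-type 190 (0.371), knockout 175 (0.464) or knockout 191 (0.0867), and NRF2 without wild-type 176 (0.0765), wild-type 177 (0.643), knockout 175 (0.200) or knockout 191 (0.0867). Without 1 library, 1 list passed (wild-type 176), 1 (wild-type 177), 8 (wild-type 190), 2 (knockout 175), 10 (knockout 179) or 0 (knockout 191).

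**Figure D4:**
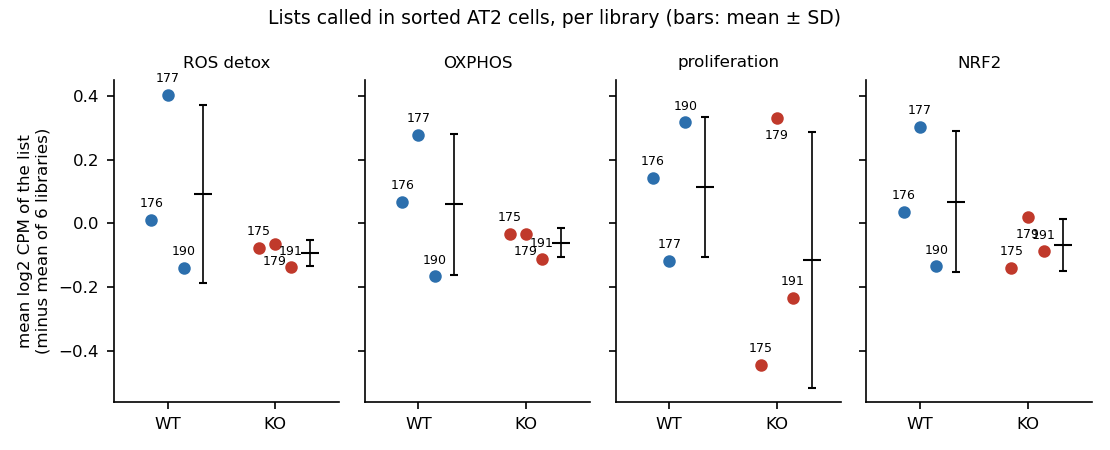
Mean log2 CPM of 4 lists in each sorted AT2 library, relative to the mean of the 6 libraries, for 3 wild-type and 3 knockout mice, with 1 point per library and group mean ± SD. For the antioxidant, respiration and NRF2 lists wild-type 177 lies above the other libraries.

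The remaining 28 tested lists did not pass in AT2 cells. Adjusted p was 0.0680 for RAS-MAPK output, the unfolded protein response and MHC class II, 0.0792 for regulatory T cell and neuroendocrine genes, 0.0866 for MHC class I, 0.120 for glycolysis, 0.127 for cholesterol and 0.155 for B and plasma cells. Among B and plasma cell genes Igha rose adjusted over the list alone and passed without the filter on low counts (adjusted p = 0.000181). Igha was near the floor, at 1.84 CPM in knockout and 0.134 CPM in wild-type cells and at most 2.57 CPM in any library. Adjusted p was 0.260 for the AT2, oxidant-producing and early stress lists, in the last of which Hspa1a rose adjusted over the list alone and Hspa1b passed without that filter (1.09e-06). It was 0.372 for neutrophil and lipid synthesis genes, 0.409 for the transitional state, 0.437 for DNA repair, 0.533 for endothelium, 0.637 for monocytes, 0.671 for plasticity, 0.695 for club cells, 0.737 for NF-kB inflammation, 0.851 for p53 targets, 0.858 for interferon and AT1 genes, 0.881 for ciliated cells, 0.931 for Mediator, 0.939 for matrix genes and 0.980 for alveolar macrophages. Median, mean and test differed in sign for the ciliated (-0.01, 0.15, up), plasticity (-0.13, 0.02, down), interferon (both below 0, up), NF-kB (0.06, -0.05, up) and Mediator (-0.02, 0.00, up) lists and for matrix genes (median above 0, test down). The other 11 lists, those of T, resident T, cytotoxic, dendritic, basal, mesenchymal, muscle, mesothelial, fat and erythroid cells, had too few members expressed. With a filter of 5 CPM, MHC class I passed (0.0466). Without wild-type 190, RAS-MAPK output (0.0262), unfolded protein response (0.0119), MHC class I (0.0144), MHC class II (0.0497) and regulatory T cell genes (0.0371) passed. Without knockout 179, neuroendocrine (0.00666), regulatory T cell (0.0470), B and plasma cell (0.00230), neutrophil (0.00761), cholesterol (0.0101) and unfolded protein response genes (0.00361) passed.

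The third comparison asked whether AT2 cells of knockout mice already differed in the genes that differed in the tumours. Of the 500 genes of smallest p that were higher in tumours, 384 were tested in AT2 cells, and 192 of these were higher in knockout cells (mean log2 fold change 0.01, adjusted p = 0.954 with camera, 0.966 with an estimated correlation). Of the 500 that were lower in tumours, 228 were tested and 136 were higher in knockout cells, the direction opposite to that in tumours (median 0.06, mean 0.13, adjusted p = 0.0632, 0.652 with an estimated correlation). That set passed without wild-type 176 (0.0187), wild-type 190 (0.0438), knockout 179 (0.0187) or knockout 191 (0.00433), and had an adjusted p of 0.628 without wild-type 177 and 0.738 without knockout 175. It also passed with no limit on the size of the sets (0.00901) and without members of the cell-type lists (0.0366). Across the 13786 genes tested in both tables, which are not independent replicates, the log2 fold changes had a Pearson r of -0.0822 and a Spearman rho of -0.0629.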

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

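Removing the length trend, leaving out both libraries of mouse 217 and the mouse number range as a covariate for the AT2 lists were chosen after seeing the data, and the other settings before the data were examined. For tumour against adjacent tissue edgeR called 2007 genes (571 higher, 1436 lower). DESeq2 called 3728 (1033 higher, 2695 lower), among them 2004 of the 2007, and limma-voom 2951 (859 higher, 2092 lower). The fit with the mouse as a block called 2980 (1113 higher, 1867 lower). The cause of these larger counts was not tested. With fewer samples fitted, the count was 847 without both libraries of mouse 217 (149 higher, 698 lower) and 598 to 1854 with 1 library left out (137 to 461 higher, 461 to 1393 lower). The remaining settings stayed within 1.5 times of the 2007: 1968 genes with DESeq2 size factors, 2233 with library totals, 1557 without a filter, 1545 with a filter of 5 CPM, 2326 without the length trend and 2007 at 2-fold. Of the 25 lists, 0 passed with an estimated correlation. With fry 15 lists passed, 14 of the 25 and the Mediator list. The cause was not tested. From 21 to 29 lists passed with 1 library left out and 24 to 27 in the other settings run.

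In AT2 cells edgeR called 0 genes (347 at an unadjusted p under 0.05), DESeq2 1 (lower, 1) and limma-voom 1 (lower, 1). Without a filter edgeR called 17 (11 higher, 6 lower), and with 1 library left out 0 to 1 (0 to 1 higher). It called 0 in the other settings. Why the filter matters was not tested. Of the 4 lists, 0 passed with an estimated correlation, 0 with fry and 2 without the length trend, and 0 to 10 lists passed with 1 library left out. The cause was not tested. A filter of 5 CPM gave 5 lists, and DESeq2 size factors and the mouse number range 4 each. Of the 2 sets of tumour genes tested in AT2 cells 0 passed, against 1 without members of the cell-type lists (adjusted p of the tumour-lower set 0.0366), 1 with no limit on set size (0.00901) and 0 to 1 with 1 library left out (0.00433 to 0.738). The other settings gave that set 0.0624 to 0.679, and the tumour-higher set 0.355 to 0.967 throughout. The cause was not tested.

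Among the lists and the genes named by the rule, none that was called changed direction in any setting. For most other called genes the direction was not compared between settings. Of the 198 lung genes named by the rule, DESeq2 kept 157 on the same side of the threshold (41 gained), limma-voom 158 (32 gained, 8 lost) and the mouse block 157 (32 gained, 9 lost). DESeq2 size factors kept 196, library totals 176 (15 gained, 7 lost) and no filter 186 (12 lost). Leaving out 1 library lost 15 to 69. Of the 166 AT2 genes named, 5 gained without a filter and none changed in the other settings. The mouse block changed no other call of a gene or list given in the text than those printed beside them, and moved member counts printed without it by at most 1.5 times. The 12 libraries were not fitted together, because the tables do not list the same genes, and sex was not a covariate, because all animals were male. Depth limits genes near 0, the AT2 libraries holding at most 18913242 counts. In sorted AT2 cells 11 of the lists, all of other cell types, had too few members expressed to be tested, and whether depth plays a part was not tested.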

Other observations

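The tests of levels against sorted AT2 cells, of the length trend in tumours, of cholesterol genes and of the AT2 lists in parts were chosen after the results were seen. The counts of other splits and both tests of the 4 AT2 lists together were written before.

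Some of the most abundant transcripts that rose in tumours stood in no list and were chosen after their values were seen. Trf, transferrin, the iron carrier of plasma, averaged 23423 ± 4254 CPM in tumours and 489 ± 44.3 CPM in adjacent tissue (log2 fold change 5.58 ± 0.51, adjusted p = 0.00592 with edgeR), against 13.7 and 16.9 CPM in knockout and wild-type AT2 cells. Ros1, a receptor tyrosine kinase, was at 184 ± 33.5 against 1.73 ± 1.39 CPM (6.73 ± 0.69, adjusted p = 0.00592) and at 41.8 and 46.7 CPM in the AT2 groups. Clu, clusterin, a secreted chaperone, was at 4367 ± 2371 against 343 ± 109.6 CPM (3.67 ± 0.62, adjusted p = 0.0147), and at 159 and 153 CPM in AT2 cells. Trf and Ros1 passed in every fit with 1 library left out, and Clu did not without adjacent 102, adjacent 217 or adjacent 224 (adjusted p up to 0.0560). Meg3 was at 3.98 and 3.31 CPM and Rian at 1.23 and 1.35 CPM in knockout and wild-type AT2 cells. The AT2 levels come from a table normalised on its own and were not tested against the lung.

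Single mice differed from the others in both of their lung libraries, in genes picked after seeing the values. Ighg1, an IgG heavy chain, was at 433 and 1022 CPM in the tumour and adjacent tissue of mouse 217 and at 1.71 to 23.6 CPM in the other 4 lung libraries. Ngp and Camp, granule proteins of immature neutrophils, were at 8.42 and 90.2 CPM and at 4.27 and 40.7 CPM in the same 2 libraries. On the lower side, 13 genes of at least 2 CPM in the other 4 libraries were over 8-fold lower in both libraries of mouse 217, against 5 over 8-fold higher. Nnt, a mitochondrial transhydrogenase, had 0 counts in both and 1248 to 2014 counts in the other 4, and Itgav, an integrin subunit, was at 2.23 and 1.99 CPM against 48.9 to 83.6 CPM. In the sorted AT2 libraries, which come from other mice, Nnt was low as well, at 0.494 to 1.39 CPM. Itgav was at 46.6 to 86.6 CPM there. A low Nnt level was thus not particular to mouse 217, and its cause was not tested. Mouse 102 had 1 gene lower and 3 higher by the same rule, and mouse 224 had 6 and 3. Dbp, a transcription factor of the circadian clock, was at 83.1 and 77.6 CPM in the libraries of mouse 224 and at 1.78 to 7.0 CPM in the other 4.

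The 6 lung libraries can be split 3 against 3 in 10 ways, as can the 6 AT2 libraries, so the share of splits is never under 0.1. In the lung, 1 of the 10 splits, the real one, gave as many as 2007 genes, and the highest of the others gave 0. For lung lists it was also 1 of 10, with 25 lists against at most 24. Every other lung split has tumours and adjacent tissue on both sides. The difference between them then adds to the spread within each side, so the 0 genes are not the level that chance alone would give. The 3 other splits that part all 3 mouse pairs each exchange tumour and adjacent labels in 1 mouse, and gave 0 genes and 13, 24 and 17 lists. In AT2 cells all 10 splits gave as many genes as the real 0, the highest other being 1. For AT2 lists 6 of 10 gave at least the real 4, so other splits can give more lists than the real one. The highest was 10, with wild-type 176, wild-type 177 and knockout 179 on one side, and its cause was not tested. For the tumour gene sets 6 of 10 gave an adjusted p as small as 0.0632, the smallest other being 0.000558.

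The 571 genes higher in tumours could come from more AT2 cells in the tumour, from the length trend of the libraries or from a change within the tumour cells. Of the higher genes found in both tables, 51.75% (295 of 570) had a tumour mean over 2 times the highest sorted AT2 library. The share was 28.7% of all tested genes and 41.98% of the genes lower in tumours (599 of 1427). The contrast with all tested genes therefore carries little weight. The 295 genes argue against more AT2 cells as the whole cause only in that they lay above both adjacent tissue and sorted AT2 cells. Once the length trend was removed, 98.599% (563 of 571) were still called higher. The trend had the same sign in tumour and adjacent tissue of each mouse. Its rho was 0.219 and 0.214 in mouse 102, -0.268 and -0.326 in mouse 217, and 0.137 and 0.0489 in mouse 224. It was thus a weak candidate for a difference between the groups, and the share kept adds little. In 61.4% (350 of 570) the lowest sorted AT2 library lay at or above the adjacent mean, against 23.69% of all tested genes. Genes picked for an adjacent mean under the tumour mean reach this more often whatever the cause. A larger share of AT2 cells may still add to many of the higher genes. Levels here come from separately normalised tables and from mice of different ages, and a change within the tumour cells stays open as untested.

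The 1436 genes lower in tumours may reflect fewer cells of other types in the tissue taken. For 87.81% of those in both tables (1253 of 1427) the highest sorted AT2 library lay under 0.5 times the adjacent mean, against 31.88% of all tested genes, as such a loss needs. These genes were picked for an adjacent mean above the tumour mean, which raises that share whatever the cause. The contrast with all tested genes thus does not single out such a loss. The same explanation is argued against for the cholesterol list, where 18 of 20 members had a lowest sorted AT2 library at or above the adjacent mean, so that fewer other cells would not lower them. Sqle, squalene epoxidase, was at 20.4 CPM in tumours, 65.4 CPM in adjacent tissue and 131 to 213 CPM in the sorted AT2 libraries. For these genes, as for the other lower ones, a difference within the tumour cells stays open as untested, and so do age and sorting, which also differ between the tables.

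The 4 lists lower in knockout AT2 cells could come from 1 library, wild-type 177, from the length trend or from the genotype. Over the 4 together, a median of 17.1% of the mean log2 fold change was left without wild-type 177, which leaves that library open since proliferation moved the other way, and 82.355% without the length trend, with over 80% left in 3 of 4 lists, which argues against the trend as the whole cause. Taken apart, the antioxidant, NRF2 and respiration lists keep a median of 17.01% without wild-type 177, so that library may carry most of their difference, while the length trend (82.07% left, 59.9% for respiration) cannot be told apart from other causes because the lists fall on both sides of 80%. With the trend removed, respiration went from -0.14 (SD over members 0.138) to -0.09 (0.135) and NRF2 from -0.16 (0.256) to -0.13 (0.241), and both calls ended, the means being smaller and the spread about as wide. The proliferation list kept 131.7% without wild-type 177 and 97% without the trend, which argues against both, but 35.06% without knockout 175 and 240.8% without knockout 179, and an effect of the genotype stays open as untested.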
